A study of Homo sapiens with 9 samples.

How the data were processed

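RNA was measured in 9 libraries of SH-SY5Y cells (written so in the labels' protocols, and SHY5Y in the titles) carrying the TDP-43 reporter: 3 from untreated cells, 3 from cells given TDP-43 aggregates and 3 from the mScarlet group. Per the labels' protocols, RNA was extracted with a column kit for small samples and libraries were made by Smart-seq2. Per the submitters' processing notes, reads were checked with FastQC, aligned with STAR to GRCh38.p13 and counted per gene with featureCounts, without versions. Per the labels and the file headers, the deposited values are normalized counts. This signal is the read count of a gene divided by a size factor per library, made by the authors before the values were deposited, per the file headers. The annotation, the strand setting and the method behind the size factors are not given in the sources used here.

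Each library's values turned out to be whole multiples of a library-specific step, so that read counts divided by a size factor were recovered by dividing by that step (100% of values whole, tolerance 1e-06). Totals, depth and the counts given to edgeR and DESeq2 come from these recovered reads. The 9 libraries held 21057 gene IDs, of which 21032 had a symbol, and totals of 28.7 to 40.4 M reads. Size factors ran from 0.7536 to 1.23. Between libraries of the same group the chi-square per gene was 12.5 to 162, so no library duplicated another of its group. Libraries of different groups were not compared in this way. There are no molecular identifiers in these values, so counting intervals and floors cover counting error only.

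The comparisons, the tests, the alternatives, the 27 gene lists and the rule for named genes were set before the data were examined. Genes with a normalized count of at least 10 in at least 3 libraries were tested (14039). Values were taken as log2(normalized count + 1) and fitted with limma 3.58.1 in R 4.3.3, by group over all 9 libraries, with moderated tests that allow for a trend with level (residual degrees of freedom 6, or 4 with a block) and Benjamini-Hochberg adjustment at 0.05. Fold changes are log2 differences with the standard error of that fit, and p-values of single genes are limma's adjusted p throughout. For a gene with no reads in a group, the fold is a lower bound against 3 reads per library, averaged over the group as normalized counts; with 1 to 3 reads, the ratio is given with a 95% counting interval.

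Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the 27 lists within each comparison. Camera asks whether a list stands above or below the other genes, and with few libraries a preset correlation can understate how far list members move together, so each call is printed beside the result with an estimated correlation. Members are counted as past the test over all genes and, separately, adjusted over the list alone. Some genes belong to more than 1 list.

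Named genes were the 10 largest rises and the 10 largest falls of each comparison among those past the test, with the same direction in all 3 pairs of same-numbered libraries, a mean of at least 50 normalized counts in the higher group and a regular gene symbol. TARDBP, STMN2, UNC13A, KALRN and ELAVL3 were named in every comparison. For each list up to 4 members past the test were eligible, or the 2 with the highest level as values where none passed. Some genes that the rule names are not reported here. Genes with exons that overlap another gene by at least 50 bases, or with near-identical copies, are given as uncertain. Coordinates come from GENCODE 29 on GRCh38.

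The labels give the replicate number as the batch, so the numbers pair the libraries. Deviations from the group means correlated at 0.15 to 0.55 in the 9 pairs with the same number and at -0.44 to 0.20 in the 18 pairs with other numbers. The fit by group alone was the design set beforehand, and the fit with the replicate number as a block is printed beside results whose call it changes or whose count it moves by over 1.5 times. On simulated counts for mScarlet against aggregates (14039 genes, 100 changed 2-fold and 100 changed 4-fold) without batch effects, the fit by group recovered 62% of the 2-fold and 98% of the 4-fold changes with 8 false calls, and the fit with the block 56% and 98% with 7. With batch effects the fit by group recovered 46% and 96% with 0 false calls, and the fit with the block 89% and 100% with 15.

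Alternatives were the block, pseudocounts of 0.5 and 5, other filters, rescaling by TMM, by median-of-ratios or by quantiles, a fit to the 2 groups compared, library weights, edgeR 4.0.16 (quasi-likelihood test, with and without the block) and DESeq2 1.42.0 (Wald test) on recovered reads, other list tests (camera with an estimated correlation, fry) and leaving out each library in turn. Chosen after the data were seen were removal of each library's trend with GC content and transcript length (loess, span 0.3, for the 13962 genes, 99.5% of those tested, with both values), a fit without batch 1, and a second way to weight libraries. Overlap between comparisons that share the untreated libraries is set beside the overlap of independent lists and beside 100 simulations of unchanged groups. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Sequence reads were not used here, so cryptic exons, splicing and the reporter transcript were not analysed here.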

Results

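TDP-43, encoded by TARDBP, is an RNA-binding protein that keeps cryptic exons out of mRNAs, and in amyotrophic lateral sclerosis and frontotemporal dementia it leaves the nucleus and aggregates. The series asked which changes in gene activity go with the loss of TDP-43 function that is seeded by aggregated TDP-43. The cells were SH-SY5Y, a human neuroblastoma line whose cultures consist mainly of adrenergic, neuroblast-like cells and can also hold flat, substrate-adherent cells called S-type. They carried a reporter that yields the red fluorescent protein mScarlet when a cryptic exon repressed by TDP-43 is included, so that fluorescence marks cells in which TDP-43 function is low. Per the labels, adding aggregates tagged with the green dye Atto 488 switched the reporter on in 0.1 to 0.2% of the cells.

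RNA sequencing libraries made by the Smart-seq2 protocol covered 3 groups of 3 libraries: untreated cells, cells given aggregates, and a group titled mScarlet activation, called mScarlet here. The titles place reporter activation in the mScarlet group, whereas its treatment label names aggregates plus transduction of an mScarlet plasmid. How its cells were set apart, for example by sorting, is not given in the sources used here, so the reporter state and any handling given to that group alone cannot be separated. Each group held replicates numbered 1 to 3, and the labels give the same number as the batch. The sources used here do not say whether replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

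Whole reads recovered from the normalized counts totalled 37.1 ± 3.16 M per untreated library, 35.5 ± 2.19 M per aggregates library and 30.7 ± 2.48 M per mScarlet library (SD, n = 3 each), with a range of 28.7 to 40.4 M. Genes with at least 1 read numbered 15833 ± 165 in untreated, 15964 ± 181 in aggregates and 15372 ± 239 in mScarlet libraries. Mitochondrial transcripts, whose share can follow RNA quality, took 4.44 ± 0.612% of reads in untreated, 4.58 ± 0.841% in aggregates and 4.13 ± 1.48% in mScarlet libraries. The first principal component held 45.6% of the variance and the next 21.1%. Libraries differed more in GC content within groups than between them: the Spearman correlation across genes between a gene's deviation from its mean and its GC content was -0.31, 0.20 and 0.09 in untreated replicates 1 to 3, -0.54, 0.31 and 0.57 in aggregates replicates and -0.42, -0.23 and 0.37 in mScarlet replicates.

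The comparison of aggregates with untreated cells asks what goes with exposure to the aggregates. The sources used here do not say whether these libraries held whole cultures or selected cells. By the fit set beforehand 6 genes rose and 1 fell among 14039 tested, against 218 and 16 with the replicate number as a block. ANXA1, which encodes the calcium-dependent phospholipid-binding protein annexin A1, rose from 2.47 ± 2.87 to 78.6 ± 13.9 normalized counts (SD, n = 3 each), and CFI, the protease complement factor I, rose from 23.0 ± 20.4 to 264 ± 74.5. MGP, the calcification inhibitor matrix Gla protein, rose from 1982 ± 888 to 11130 ± 4809, and GPNMB, a transmembrane glycoprotein of melanosomes and lysosomes, rose from 375 ± 55.6 to 1564 ± 422. RNF212, a ring finger protein of meiotic recombination, fell from 105 ± 10.7 to 10.9 ± 1.75.

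On the log2(normalized count + 1) scale, which understates the change of low genes, ANXA1 was higher by 4.90 ± 0.72 (SE; limma adjusted p = 0.046) and CFI by 3.79 ± 0.53 (limma adjusted p = 0.0424). MGP was higher by 2.46 ± 0.36 (limma adjusted p = 0.046) and GPNMB by 2.03 ± 0.26 (limma adjusted p = 0.0384). EVA1A, which encodes a membrane protein linked to autophagy, rose by 2.57 ± 0.35, and OLFML3, a secreted olfactomedin-domain protein, rose by 2.09 ± 0.25 (limma adjusted p = 0.0384 for both). RNF212 fell by 3.15 on this scale, with an SE of 0.42 (limma adjusted p = 0.0384). All 7 genes moved the same way in each of the 3 batches, and each passed in 3 of the 9 fits that left out a library. In the GRCh38 annotation ANXA1 lies on chromosome 9 from 73151757 to 73170393, CFI on chromosome 4 from 109740694 to 109802179, MGP on chromosome 12 from 14881181 to 14885926 and GPNMB on chromosome 7 from 23235967 to 23275108. Exons of MGP overlap C12orf60 on the opposite strand, and since the strand setting of the counting is not given in the sources used here its value is uncertain.

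At an unadjusted p under 0.05, 492 genes differed, and with the replicate number as a block limma called 234 genes, 218 higher and 16 lower, all 7 among them. No gene passed without untreated replicate 1 or 3, without aggregates replicate 1 or 2, or without mScarlet replicate 2 or 3, which enter through the shared spread, whereas 32 genes passed without untreated replicate 2, 91 without aggregates replicate 3 and 15 without mScarlet replicate 1.

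Of the 27 gene lists, 4 stood above and 4 below the other genes by camera in aggregates against untreated cells. Of 24 measured markers of mesenchymal, S-type cells, 1 rose, ANXA1, against 11 adjusted over the list alone and 7 with the block. The median log2 change was 0.69 (camera adjusted p = 1.08e-19; adjusted p = 0.138 with an estimated correlation). Of 30 interferon response genes none passed, against 7 adjusted over the list alone and 5 with the block, and the median was 0.39 (camera adjusted p = 1.45e-12; adjusted p = 0.138 with an estimated correlation). Its most abundant member, B2M, the light chain of MHC class I, stood at 0.66 ± 0.23 (limma adjusted p = 0.754). Of 16 NF-kB and inflammatory genes none passed, against 2 adjusted over the list alone and 2 with the block. The median was 0.23 (camera adjusted p = 0.00133; adjusted p = 0.308 with an estimated correlation). CCL2, a monocyte-attracting chemokine of that list, stood at 1.85 ± 0.54 (limma adjusted p = 0.41), and with the block it passed (limma adjusted p = 0.0056). Of 37 lysosome genes none passed, also over the list alone, and 2 passed with the block. The median was 0.10 (camera adjusted p = 0.00318; adjusted p = 0.36 with an estimated correlation).

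The lists below the other genes held no member that passed, over all genes or adjusted over the list alone. Their median log2 changes were -0.13 for 30 hnRNP and SR splicing factors (camera adjusted p = 7.46e-06; adjusted p = 0.258 with an estimated correlation) and -0.09 for 20 stress granule proteins (camera adjusted p = 0.00318; adjusted p = 0.138 with an estimated correlation). The median was -0.13 for 26 adrenergic neuroblast markers (camera adjusted p = 0.00318; adjusted p = 0.423 with an estimated correlation), of which 2 were higher with the block. It was -0.10 for 41 genes of G2 and M phase (camera adjusted p = 0.0274; adjusted p = 0.838 with an estimated correlation). HNRNPA1, an abundant splicing factor, stood at -0.16 ± 0.14 (limma adjusted p = 1), and CHGA, the secretory granule protein chromogranin A, at -0.48 ± 0.19 (limma adjusted p = 1). With the block, heparan sulfate proteoglycans also passed upward (camera adjusted p = 0.0192 against 0.0511 without it) and ribosomal proteins downward (camera adjusted p = 0.00629 against 0.0785). For these the adjusted p = 0.267 and 0.866 with an estimated correlation. Glycolysis and hypoxia genes passed downward with the block once GC and length trends were removed (camera adjusted p = 0.037 against 0.239; adjusted p = 0.823 with an estimated correlation). The splicing factor, interferon and mesenchymal calls held without any 1 library, whereas the adrenergic call was lost without untreated replicate 2 (camera adjusted p = 0.0966) or aggregates replicate 1 (0.759), the G2 and M call without untreated replicate 2 (0.949), untreated replicate 3 (0.185) or aggregates replicate 1 (0.278), the lysosome call without untreated replicate 2 (0.0966), and the NF-kB and stress granule calls without aggregates replicate 1 (0.0619 and 0.0881).

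The comparison of mScarlet with aggregates cells asks what goes with the reporter activation, or plasmid transduction, that the labels give for the mScarlet group, since both groups had received aggregates. The chemokine genes CXCL8, CCL5, CXCL11 and CCL7 were among the 10 largest named rises. CXCL8, the neutrophil-attracting chemokine interleukin 8, had no reads in the aggregates libraries and 389 ± 229 normalized counts in the mScarlet libraries (SD, n = 3 each), and was at least 138-fold higher against a floor of 3 reads per library. CCL2 rose from 367 ± 230 to 4694 ± 706. CD44, the hyaluronan receptor and a mesenchymal marker, rose from 107 ± 18.1 to 808 ± 80.2, and ACTA2, smooth muscle actin, from 413 ± 131 to 2721 ± 221. Falls were smaller, and CHGA fell from 30820 ± 7594 to 15740 ± 759.

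Among the other chemokine genes, CCL5 was at least 24.3-fold higher and CXCL11 at least 20.3-fold higher against the same floor, both without reads in the aggregates libraries (limma adjusted p = 0.0036 and 0.00997). CCL7 rose by 4.79 ± 0.96 on the log2 scale (SE; limma adjusted p = 0.0423), and TNFRSF9, a T-cell costimulatory receptor of the TNF family, rose by 5.01 ± 0.67 (limma adjusted p = 0.00854). The log2 change was 3.91 ± 0.54 for CCL2 (limma adjusted p = 0.00909). CXCL8, whose size is given above as a lower bound, passed with limma adjusted p = 0.000152. PTGS2, the inducible cyclooxygenase, was at least 13.6-fold higher (limma adjusted p = 0.00604). HSPA6, a strictly stress-inducible HSP70, had 1 read over the aggregates libraries and 791 over the mScarlet libraries, a ratio of 985 with a 95% counting interval of 176 to 39000 (limma adjusted p = 0.00274). MID2, a ubiquitin ligase that binds microtubules, was at least 21.5-fold higher, HKDC1, a hexokinase, rose by 4.92 ± 0.73, IPCEF1 by 4.85 ± 0.71 and the urea transporter gene SLC14A1 by 4.40 ± 0.86 (limma adjusted p = 0.00997, 0.0114, 0.0108 and 0.0365). Exons of IPCEF1 overlap OPRM1 and those of ACTA2 overlap FAS, in each case on the opposite strand, and HSPA6 shares sequence with other HSP70 genes, so these values are uncertain. In the GRCh38 annotation CXCL8 lies on chromosome 4 from 73740506 to 73743716, CCL2 on chromosome 17 from 34255218 to 34257203 and its neighbour CCL7 from 34270221 to 34272242, and CD44 on chromosome 11 from 35138870 to 35232402.

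**Figure D1:**
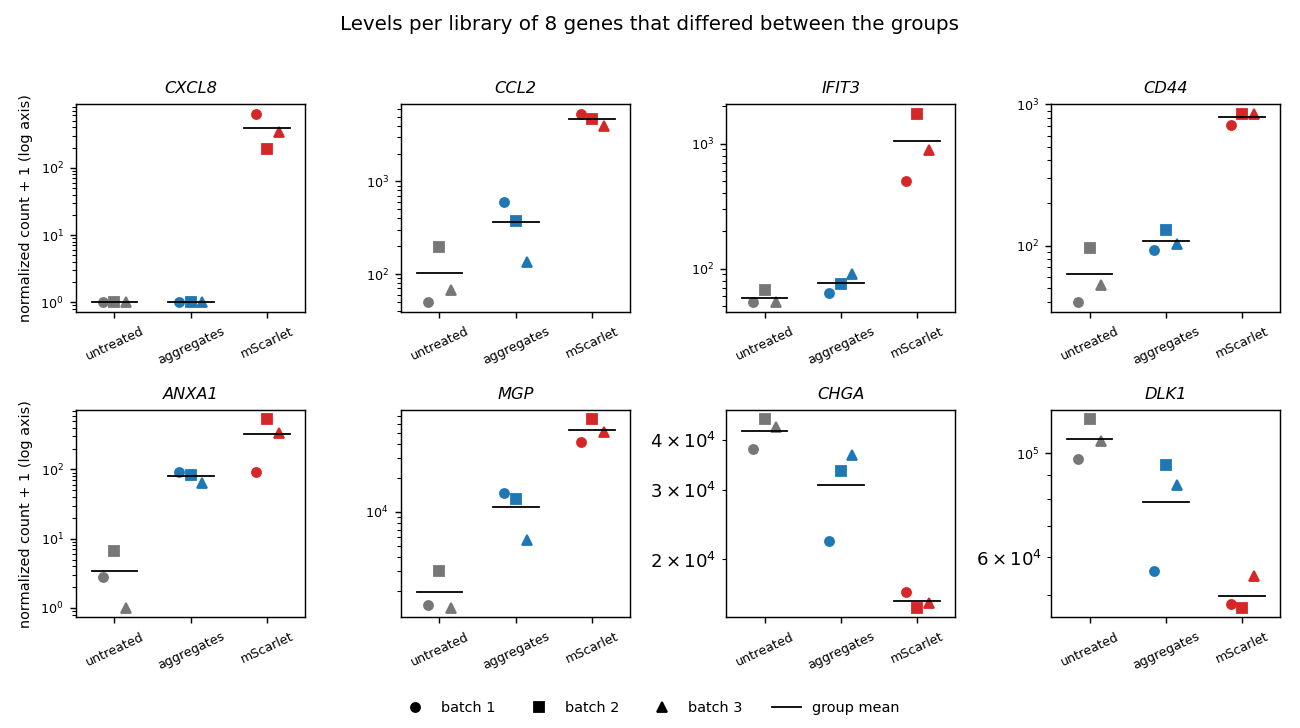
Normalized counts plus 1 (log axis) of 8 genes in each of the 9 libraries, grouped by treatment, with a marker shape per batch and a line at the group mean. CXCL8 lies at 0 counts in all 6 untreated and aggregates libraries, CCL2, IFIT3, CD44 and MGP are higher and CHGA and DLK1 lower in each mScarlet library than in the untreated library of its batch, and ANXA1 is higher in both treated groups.

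Of the falls, ZNF417, a zinc finger gene, fell by 1.80 (limma adjusted p = 0.039) and CC2D1A, a signalling scaffold and transcriptional repressor gene, by 1.75 on the log2 scale (limma adjusted p = 0.0461). SETD2, the histone H3 lysine methyltransferase, fell by 1.05 and CHD8, a chromodomain helicase, by 0.92 (limma adjusted p = 0.0314 and 0.0448). NT5C1A, a cytosolic nucleotidase gene, fell by 1.12 and CHGA by 0.94 (limma adjusted p = 0.0423 for both). TTC21A, ZCCHC12, HSPA12A and PCDHB14 made up the rest of the 10 named falls, with log2 changes of -1.22, -0.93, -0.78 and -0.77. Exons of CC2D1A, TTC21A and HSPA12A overlap genes on the opposite strand, which leaves their values uncertain.

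In all, 115 genes rose and 13 fell between mScarlet and aggregates cells, and 2337 differed at an unadjusted p under 0.05. With the replicate number as a block limma called 2864 genes, 1473 higher and 1391 lower, all 128 among them. The count was 1358 without aggregates replicate 1, 43 without aggregates replicate 2, 44 without aggregates replicate 3, 17 without mScarlet replicate 2 and 34 without mScarlet replicate 3. Of 34 named genes that passed, 7 passed without any 1 of the 9 libraries, namely ACTA2, CCL5, CD44, CXCL8, HSPA6, IFIT3 and PTGS2. The direction held in all 34, which was likely beforehand, since these genes were picked for passing.

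The inflammatory, interferon and mesenchymal lists stood above the other genes in mScarlet against aggregates cells. Of 16 NF-kB and inflammatory genes 6 rose, against 11 adjusted over the list alone and 9 with the block. The median log2 change was 1.41 (camera adjusted p = 3.9e-11; adjusted p = 0.114 with an estimated correlation). A further 9 listed genes, TNFAIP3, TNF, IL6, IL1B, IL1A and the chemokine genes CXCL1, CXCL2, CXCL3 and CCL20, were not tested. They were not among the genes with at least 10 normalized counts in at least 3 libraries. CXCL8 and PTGS2, at 0 in the untreated and aggregates libraries, met that filter through the mScarlet libraries alone. The count, median and camera result of this list thus rest partly on members kept because they were high there. Of 30 interferon response genes 3 rose, against 14 higher and 1 lower adjusted over the list alone and 13 higher and 1 lower with the block. The median was 0.66 (camera adjusted p = 8.87e-08; adjusted p = 0.318 with an estimated correlation). The genes were IFIT3, an interferon-induced inhibitor of viral RNA translation, from 75.2 ± 13.5 to 1041 ± 631 (log2 change 3.61 ± 0.38, limma adjusted p = 0.00274), IFI44 at 2.88 ± 0.48 and IFIT1 at 2.26 ± 0.39 (limma adjusted p = 0.0187 and 0.0214). Of 24 mesenchymal markers 3 rose, against 9 higher and 1 lower adjusted over the list alone and 13 higher and 1 lower with the block. The median was 0.83 (camera adjusted p = 1.11e-06; adjusted p = 0.375 with an estimated correlation). They were CD44 at 2.91 ± 0.31, ACTA2 at 2.77 ± 0.31 and LGALS1, galectin 1, at 0.86 ± 0.17 (limma adjusted p = 0.00274, 0.00319 and 0.0406). TRAF1, a TNF receptor adaptor, rose by 2.97 ± 0.50 (limma adjusted p = 0.0206).

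Of 35 genes of the unfolded protein response and ATF4 targets 1 rose, the cystine transporter gene SLC7A11, at 2.15 ± 0.34 (limma adjusted p = 0.0156), against 5 adjusted over the list alone and 16 higher and 1 lower with the block. The median was 0.35 (camera adjusted p = 8.98e-07; adjusted p = 0.318 with an estimated correlation). Of 26 p53 targets and apoptosis genes 1 rose, PMAIP1, which encodes the BH3-only protein NOXA, at 1.26 ± 0.18 (limma adjusted p = 0.00998), against 6 adjusted over the list alone and 9 higher and 1 lower with the block. The median was 0.29 (camera adjusted p = 1.29e-05; adjusted p = 0.318 with an estimated correlation). Of 24 immediate early genes 2 rose, CCN1 at 1.69 ± 0.28 and DUSP6 at 0.81 ± 0.14 (limma adjusted p = 0.0172 and 0.0235), against 3 adjusted over the list alone and 5 higher and 1 lower with the block. The median was 0.37 (camera adjusted p = 0.00452; adjusted p = 0.425 with an estimated correlation). SDC4, the heparan sulfate proteoglycan syndecan 4, rose by 1.14 ± 0.19 (limma adjusted p = 0.0187) as 1 of 28 members, against 5 adjusted over the list alone and 7 higher and 2 lower with the block, and its list did not pass (camera adjusted p = 0.0922). That list passed upward once trends with GC content and length were removed in the fit with the block (median 0.25 against 0.08, camera adjusted p = 0.00935; adjusted p = 0.372 with an estimated correlation).

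The nuclear oxidative phosphorylation, ribosomal protein, proteasome and heat shock lists stood slightly above the other genes with no member past the test, over all genes or over the list alone. The medians were 0.32 for 51 nuclear-encoded oxidative phosphorylation genes (camera adjusted p = 8.87e-08; adjusted p = 0.434 with an estimated correlation) and 0.27 for 65 ribosomal proteins (camera adjusted p = 2.56e-05; adjusted p = 0.64 with an estimated correlation). They were 0.22 for 31 proteasome genes (camera adjusted p = 0.000642; adjusted p = 0.434 with an estimated correlation) and 0.18 for 24 heat shock genes (camera adjusted p = 0.0436; adjusted p = 0.375 with an estimated correlation). With the block 23 oxidative phosphorylation, 12 ribosomal protein and 8 proteasome genes were higher and none was lower, and of the heat shock genes 7 were higher and 2 lower. Once trends with GC content and length were removed in the fit with the block, the medians were 0.13 for oxidative phosphorylation, with 11 members higher and 1 lower, and 0.11 for ribosomal proteins. Those of the proteasome and heat shock lists were then 0.06 and 0.10, and their calls ended (camera adjusted p = 0.0649 and 0.109).

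Neuronal lists stood below the other genes. Of 40 axon and synapse genes none passed over all genes or over the list alone, and 19 were lower and 1 higher with the block. The median was -0.47 (camera adjusted p = 1.2e-05; adjusted p = 0.415 with an estimated correlation). Its most abundant members stood at 0.13 ± 0.24 (STMN1) and 0.11 ± 0.19 (SYT4), with limma adjusted p = 0.793 and 0.788, and both turned negative under quantile normalization. Of 26 adrenergic markers 1 fell, CHGA, against 3 adjusted over the list alone and 10 lower and 2 higher with the block. The median was -0.23 (camera adjusted p = 0.0106; adjusted p = 0.434 with an estimated correlation). Apart from the TDP-43 targets, given below, the remaining lists did not pass, with camera adjusted p between 0.07 for S phase and 0.991 for mitochondrially encoded mRNAs. With the block S phase (camera adjusted p = 0.017), G2 and M phase (0.0372) and stress granule proteins (0.0485) passed downward, the last not once trends with GC content and length were also removed (0.177). For these 3 with the block the adjusted p = 0.361, 0.36 and 0.329 with an estimated correlation. Once those trends were also removed, 9 S phase and 11 G2 and M genes were lower and none higher (camera adjusted p = 0.000434 and 6.51e-05; adjusted p = 0.484 and 0.442 with an estimated correlation). The adrenergic call was lost without mScarlet replicate 1 (camera adjusted p = 0.0731), the heat shock call without aggregates replicate 1 (0.264) or mScarlet replicate 3 (0.176), and the immediate early call without the same libraries (0.161 and 0.0657).

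The comparison of mScarlet with untreated cells spans aggregate exposure together with the reporter activation, or plasmid transduction, that the labels give for the mScarlet group. CXCL8, CCL7, CCL5 and CCL2 were among its 10 largest named rises. CCL2 rose from 102 ± 78.9 to 4694 ± 706 normalized counts, and VCAM1, an endothelial and stromal adhesion molecule, had 1 read over the untreated libraries and 559 over the mScarlet libraries, a ratio of 721 with a 95% counting interval of 129 to 28500. ANXA1 rose from 2.47 ± 2.87 to 320 ± 220 and CRYAB, the small heat shock protein alpha-B crystallin, from 2.80 ± 4.09 to 133 ± 65.2. CHGA fell from 42100 ± 3752 to 15740 ± 759 and DLK1, a Notch-like membrane protein of neuroendocrine cells, from 107000 ± 10550 to 49800 ± 4381 (SD, n = 3 each).

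Of the largest rises, CXCL8 was at least 144-fold and CCL5 at least 25.3-fold higher, and HSPA6 had a ratio of 1020 with a 95% counting interval of 183 to 40300 (limma adjusted p = 7.61e-05, 0.000505 and 0.00027). TNFRSF9 rose by 6.60 ± 0.67, ANXA1 by 6.59 ± 0.71, CCL7 by 5.96 ± 0.96 and CCL2 by 5.76 ± 0.54 on the log2 scale (SE; limma adjusted p = 0.00027, 0.000376, 0.00334 and 0.00018). GASK1B, a Golgi kinase-like gene, rose by 6.45 ± 0.66, and PSG4, a pregnancy-specific glycoprotein gene with close paralogs and therefore uncertain, had a ratio of 298 with a 95% counting interval of 52.9 to 11800 (limma adjusted p = 0.00027 and 0.00016). VCAM1 passed with limma adjusted p = 0.000878. Among the falls, RTL1, an imprinted retrotransposon-derived gene, went from 3427 ± 1502 to 687 ± 179 and fell by 2.23 (limma adjusted p = 0.02), and TRIM29 fell by 1.87 (limma adjusted p = 0.00304). NOVA2, a neuronal splicing factor, fell by 1.64 (limma adjusted p = 0.0126) and GABRP, a GABA receptor subunit, by 2.06 (limma adjusted p = 0.0068). Further named falls were GMCL2, AMIGO1, CC2D1A, ZNF417 and SRCAP, with log2 changes of -2.68, -2.04, -1.90, -1.64 and -1.52, of which GMCL2, with a near-identical paralog, and SRCAP, whose exons overlap TMEM265, are uncertain. CHGA lies on chromosome 14 from 92923080 to 92935293, DLK1 from 100725705 to 100738224 and RTL1 from 100879753 to 100903722.

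In all, 724 genes rose and 179 fell between mScarlet and untreated cells, and 3119 differed at an unadjusted p under 0.05. Under quantile normalization the split was 705 higher and 314 lower. With the replicate number as a block limma called 3647 genes, 1942 higher and 1705 lower, all 903 among them. The count was 534 without untreated replicate 2, 456 without untreated replicate 3, 1396 without aggregates replicate 1 and 452 without mScarlet replicate 2. Of 72 named genes that passed, 38 passed without any 1 of the 9 libraries. The direction held in all 72, which was likely beforehand, since these genes were picked for passing. Of the named genes printed here, those that failed without at least 1 library were AMIGO1, CNTN1, CTSB, DLK1, DNAJB4, FDFT1, GMCL2, GPC3, HAND1, HELLS, INA, MYC, NDRG1, NOVA2, NPY, NUP155, NUP43, P4HA1, PSMA7, PSMB3, PTBP2, RTL1, SNAP25, SRCAP, TRIB3, TUBA4A, WIPI1, XBP1 and ZNF417, of which DLK1 and HAND1 failed only without mScarlet replicate 2 (limma adjusted p = 0.059 and 0.055), GMCL2 only without untreated replicate 2 (0.0645) and NOVA2 only without untreated replicate 3 (0.0744).

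Of 16 NF-kB and inflammatory genes 10 rose in mScarlet against untreated cells, against 12 adjusted over the list alone. The median log2 change was 1.91 (camera adjusted p = 4.17e-12; adjusted p = 0.103 with an estimated correlation). Besides CXCL8 and CCL2 they included TRAF1 at 5.14 ± 0.50 (limma adjusted p = 0.000217) and PTGS2, at least 14.2-fold higher (limma adjusted p = 0.00082). CXCL8 and PTGS2 met the filter on level through the mScarlet libraries alone. The list values thus rest partly on members kept because they were high there. Of 30 interferon response genes 15 rose, against 21 adjusted over the list alone. The median was 1.29 (camera adjusted p = 2.18e-13; adjusted p = 0.142 with an estimated correlation). IFI44 rose by 4.51 ± 0.48 and IFIT3 by 3.98 ± 0.38, and the antiviral membrane protein genes IFITM3 and IFITM2, which resemble each other and are uncertain, by 3.92 ± 0.42 and 3.25 ± 0.37 (limma adjusted p = 0.00032, 0.000188, 0.00032 and 0.000493). Of 24 mesenchymal markers 13 rose, against 16 adjusted over the list alone. The median was 1.66 (camera adjusted p = 6.71e-14; adjusted p = 0.159 with an estimated correlation). ACTA2 rose by 4.01 ± 0.31, CD44 by 3.79 ± 0.31 and LGALS1 by 1.66 ± 0.17 (limma adjusted p = 7.61e-05, 8.15e-05 and 0.000273). The listed markers PRRX1, COL1A2, MEOX1, MEOX2, CAV1 and MYL9 were not tested, and CAV1 and PRRX1 stood at 0 in each mScarlet library. The mScarlet libraries thus carried both inflammatory transcripts and part of the S-type marker list above the untreated level, and had the fewest reads on average.

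Of 35 genes of the unfolded protein response and ATF4 targets 6 rose, against 14 adjusted over the list alone and 19 with the block. The median was 0.36 (camera adjusted p = 5.98e-07; adjusted p = 0.207 with an estimated correlation). SLC7A11 rose by 2.81 ± 0.34, the pseudokinase gene TRIB3 by 0.73 ± 0.18 and XBP1, the transcription factor spliced under endoplasmic reticulum stress, by 0.86 ± 0.21 (limma adjusted p = 0.000652, 0.0295 and 0.0339). Of 26 p53 targets and apoptosis genes 7 rose, against 11 adjusted over the list alone and 13 higher and 2 lower with the block. The median was 0.44 (camera adjusted p = 1.68e-05; adjusted p = 0.159 with an estimated correlation). FAS, a death receptor, rose by 2.27 ± 0.37, CASP8, the caspase it recruits, by 2.75 ± 0.52 and PMAIP1 by 1.18 ± 0.18 (limma adjusted p = 0.00373, 0.00809 and 0.00243). Exons of FAS overlap ACTA2 on the opposite strand, so the value of FAS is uncertain. Of 24 immediate early genes 3 rose and 1 fell, against 5 and 1 adjusted over the list alone and 8 and 3 with the block. The median was 0.39 (camera adjusted p = 0.00766; adjusted p = 0.354 with an estimated correlation). CCN1 rose by 3.04 ± 0.28 and MYC fell by 0.65 (limma adjusted p = 0.00016 and 0.0288). Of 28 heparan sulfate proteoglycan genes 7 rose and 1 fell, against 9 and 1 adjusted over the list alone and 10 and 4 with the block. The median was 0.16 (camera adjusted p = 0.0173; adjusted p = 0.303 with an estimated correlation). The core protein genes SDC4, SDC2 and GPC3 rose by 1.63 ± 0.19, 1.23 ± 0.20 and 1.80 ± 0.37 (limma adjusted p = 0.000524, 0.00317 and 0.0141). Of 37 lysosome genes 4 rose, against 8 higher and 1 lower adjusted over the list alone and 12 and 2 with the block. The median was 0.21 (camera adjusted p = 0.0328; adjusted p = 0.354 with an estimated correlation). The sterol carrier gene NPC2, whose exons overlap ISCA2 on the opposite strand, rose by 1.39 ± 0.23 and the cathepsin gene CTSB by 0.88 ± 0.23 (limma adjusted p = 0.00425 and 0.047).

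Of 31 proteasome genes 2 rose, also over the list alone, and 8 rose and 1 fell with the block. The median was 0.23 (camera adjusted p = 0.00153; adjusted p = 0.375 with an estimated correlation). PSMB3 and PSMA7 rose by 0.52 ± 0.13 and 0.49 ± 0.13 (limma adjusted p = 0.0403 and 0.0419). Of 51 oxidative phosphorylation and 65 ribosomal protein genes none passed, over all genes or the list alone, against 25 and 6 higher with the block, with medians of 0.33 and 0.19 (camera adjusted p = 3.95e-07 and 0.00738; adjusted p = 0.36 and 0.713 with an estimated correlation). Once trends with GC content and length were removed in the fit with the block, the proteasome (camera adjusted p = 0.0745), ribosomal protein (0.853) and nuclear transport (0.438) calls ended, with medians of 0.08, -0.01 and -0.02. The oxidative phosphorylation median was then 0.16, with 15 members higher and 2 lower, and the lysosome median 0.11.

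Neuronal and RNA-handling lists stood below the other genes in mScarlet against untreated cells. Of 40 axon and synapse genes 5 fell and 1 rose, also adjusted over the list alone, against 23 and 3 with the block. The median was -0.51 (camera adjusted p = 2.93e-05; adjusted p = 0.354 with an estimated correlation). The adhesion molecule gene CNTN1 fell by 0.97, the neurofilament-related INA by 0.85 and the synaptic SNARE gene SNAP25 by 0.53, while the sodium channel gene SCN9A rose by 1.30 ± 0.19 (limma adjusted p = 0.0116, 0.0221, 0.0202 and 0.00207). Of 26 adrenergic markers 5 fell and 2 rose, against 12 and 2 adjusted over the list alone and 15 and 2 with the block. The median was -0.36 (camera adjusted p = 0.000419; adjusted p = 0.344 with an estimated correlation). CHGA fell by 1.42, DLK1 by 1.10 and the transcription factor gene HAND1 by 0.86, while the neuropeptide gene NPY rose by 1.20 ± 0.27 (limma adjusted p = 0.00107, 0.00881, 0.00881 and 0.0226). Of 30 hnRNP and SR splicing factors 1 fell, also over the list alone, against 7 with the block. The median was -0.20 (camera adjusted p = 0.016; adjusted p = 0.354 with an estimated correlation). It was PTBP2, the neuronal polypyrimidine tract binding protein, which fell by 1.01 (limma adjusted p = 0.0147). Of 20 stress granule proteins none passed, against 2 lower adjusted over the list alone and 8 lower and 1 higher with the block. The median was -0.19 (camera adjusted p = 0.00237; adjusted p = 0.142 with an estimated correlation). Of 44 nuclear transport genes 2 fell, NUP155 by 0.53 and NUP43 by 0.55, against none adjusted over the list alone and 7 lower and 1 higher with the block. The median was -0.10 (camera adjusted p = 0.0236; adjusted p = 0.271 with an estimated correlation). Of 41 genes of G2 and M phase none passed, over all genes or the list alone, against 10 lower with the block. The median was -0.23 (camera adjusted p = 0.0103; adjusted p = 0.683 with an estimated correlation). With the block once GC and length trends were removed, 18 were lower and none higher, with a median of -0.26 (camera adjusted p = 6.36e-06; adjusted p = 0.346 with an estimated correlation).

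Apart from the TDP-43 targets, given below, the other lists did not pass by camera in this comparison. Among ALS and FTD genes 2 of 32 rose, the autophagy receptor gene SQSTM1 by 1.03 ± 0.17 and the tubulin gene TUBA4A by 1.65 ± 0.37 (limma adjusted p = 0.00368 and 0.0217; camera adjusted p = 0.212 for the list), against 2 higher and 1 lower adjusted over the list alone and 4 and 10 with the block. Of 24 heat shock genes 3 rose, also over the list alone, against 6 higher and 1 lower with the block (camera adjusted p = 0.16). CRYAB rose by 5.58 ± 0.73, HSPB8 by 1.63 ± 0.30 and DNAJB4 by 0.82 ± 0.19 (limma adjusted p = 0.000995, 0.0071 and 0.023). Of 32 autophagy genes 2 rose, also over the list alone, against 4 higher and 2 lower with the block (camera adjusted p = 0.565), SQSTM1 and WIPI1. Exons of SQSTM1, TUBA4A, CRYAB, WIPI1, DNAJB4 and NUP43 overlap other genes, which leaves their values uncertain. Of 23 cholesterol synthesis genes FDFT1 rose, against none adjusted over the list alone and 3 higher and 2 lower with the block (camera adjusted p = 0.514). Of 26 glycolysis and hypoxia genes P4HA1 rose and NDRG1 fell, against 2 and 1 adjusted over the list alone and 2 and 5 with the block (camera adjusted p = 0.544). Of 39 S phase genes HELLS fell, against none adjusted over the list alone and 4 lower with the block (camera adjusted p = 0.115, or 0.00872 with the block once GC and length trends were removed, where adjusted p = 0.572 with an estimated correlation). No gene passed among 18 nonsense-mediated decay (camera adjusted p = 0.235), 38 endocytosis and ESCRT (0.72) and 13 mitochondrially encoded genes (0.796), against 1 higher and 4 lower, 3 higher and 4 lower, and 1 higher with the block. List calls lost without a library were those for heparan sulfate and immediate early genes without untreated replicate 1 (camera adjusted p = 0.158 and 0.105), G2 and M phase without untreated replicate 2 (0.207) or mScarlet replicate 1 (0.358), splicing factors without mScarlet replicate 3 (0.101), lysosome without untreated replicate 2 (0.109) or mScarlet replicate 3 (0.209), nuclear transport without untreated replicate 1 (0.105) or mScarlet replicate 3 (0.0773), ribosomal proteins without untreated replicate 2 (0.112), untreated replicate 3 (0.567) or mScarlet replicate 1 (0.358), and TDP-43 targets without mScarlet replicate 1 (0.0505).

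**Figure D2:**
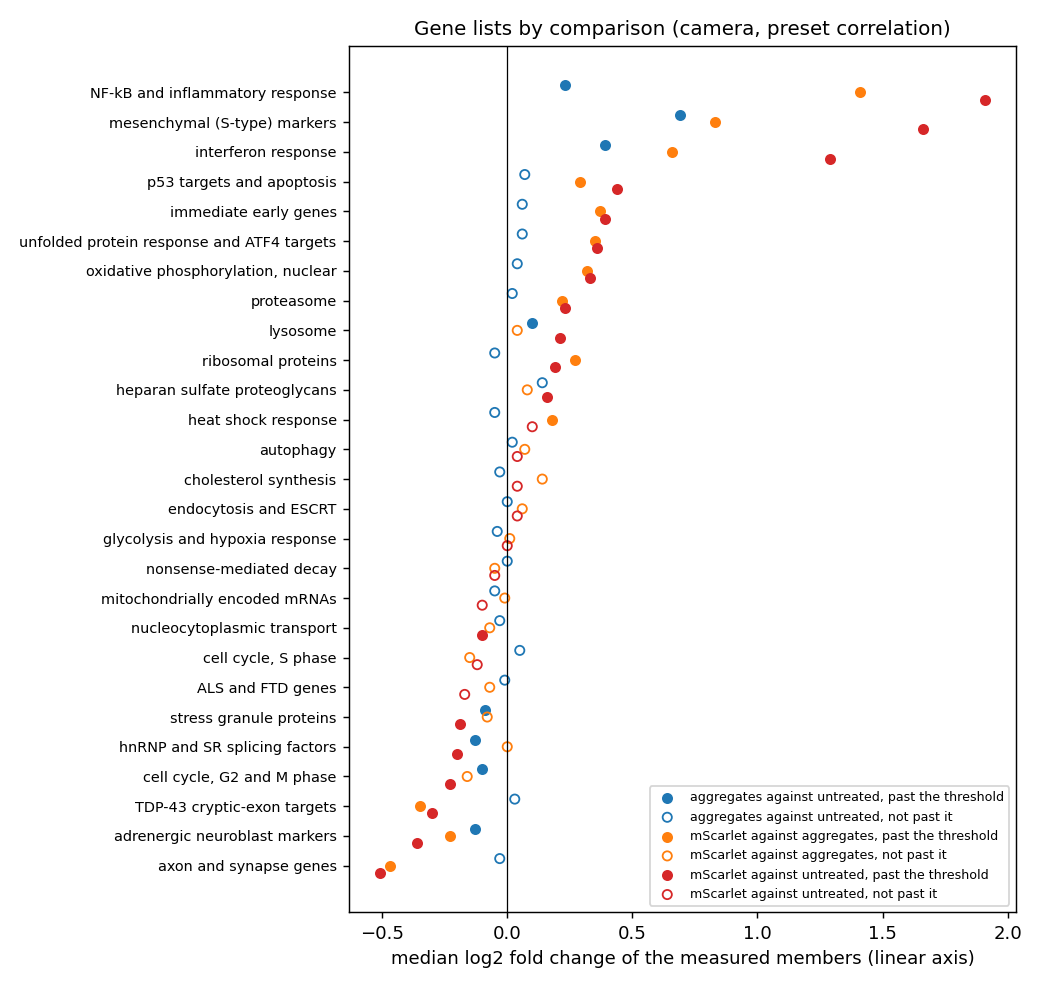
Median log2 fold change (linear axis) of the measured members of each of the 27 gene lists in the 3 comparisons, with filled points for lists past an adjusted p of 0.05 by camera with a preset correlation and open points for the others. The NF-kB, interferon and mesenchymal lists lie furthest to the right, with medians of 1.91, 1.29 and 1.66 in mScarlet against untreated cells, and the axon and synapse list furthest to the left at -0.51.

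TARDBP and the mRNAs known to change when TDP-43 function is lost were followed in every comparison. TARDBP itself stood at 7956 ± 427 normalized counts in untreated, 7192 ± 307 in aggregates and 6999 ± 446 in mScarlet libraries (SD, n = 3 each), and its log2 change of -0.18 ± 0.12 between mScarlet and untreated cells did not pass (limma adjusted p = 0.382). STMN2, an axonal microtubule regulator whose full-length mRNA falls when TDP-43 is lost from neurons, stood at 41930 ± 2417, 41320 ± 3599 and 41760 ± 4137, and its log2 change between mScarlet and aggregates cells was 0.01 ± 0.15 (limma adjusted p = 0.972), or -0.19 under quantile normalization. UNC13A, a synaptic vesicle priming factor, stood at 203 ± 86.8, 186 ± 108 and 118 ± 31.9, KALRN, a guanine nucleotide exchange factor of dendritic spines, at 180 ± 43.3, 196 ± 47.6 and 116 ± 32.3, and ELAVL3, a neuronal RNA-binding protein, at 151 ± 62.5, 127 ± 71.8 and 76.1 ± 14.9.

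Between mScarlet and aggregates cells the log2 change was -0.47 ± 0.49 for UNC13A, -0.77 ± 0.30 for KALRN and -0.52 ± 0.50 for ELAVL3, and none passed (limma adjusted p = 0.632, 0.232 and 0.605). With the block KALRN passed (limma adjusted p = 0.0197), and against untreated cells UNC13A, KALRN and ELAVL3 passed with the block (limma adjusted p = 0.0387, 0.0367 and 0.0252) and not without it (0.428, 0.228 and 0.317). Of 31 measured TDP-43 cryptic-exon targets none passed between mScarlet and aggregates cells, over all genes or adjusted over the list alone, and 12 were lower and 2 higher with the block. The median log2 change was -0.35 (camera adjusted p = 0.000642; adjusted p = 0.434 with an estimated correlation), or -0.21 with the block once GC and length trends were removed (camera adjusted p = 0.00231; adjusted p = 0.372 with an estimated correlation). Against untreated cells none passed either, over all genes or over the list alone, and 11 were lower with the block. The median was -0.30 (camera adjusted p = 0.00623; adjusted p = 0.492 with an estimated correlation). Between aggregates and untreated cells the median was 0.03 (camera adjusted p = 0.813). Counts per gene do not separate cryptic from annotated exons, so inclusion of cryptic exons was not measured. In the GRCh38 annotation TARDBP lies on chromosome 1 from 11012344 to 11026420, STMN2 on chromosome 8 from 79610814 to 79666175 and UNC13A on chromosome 19 from 17601328 to 17688365.

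**Figure D3:**
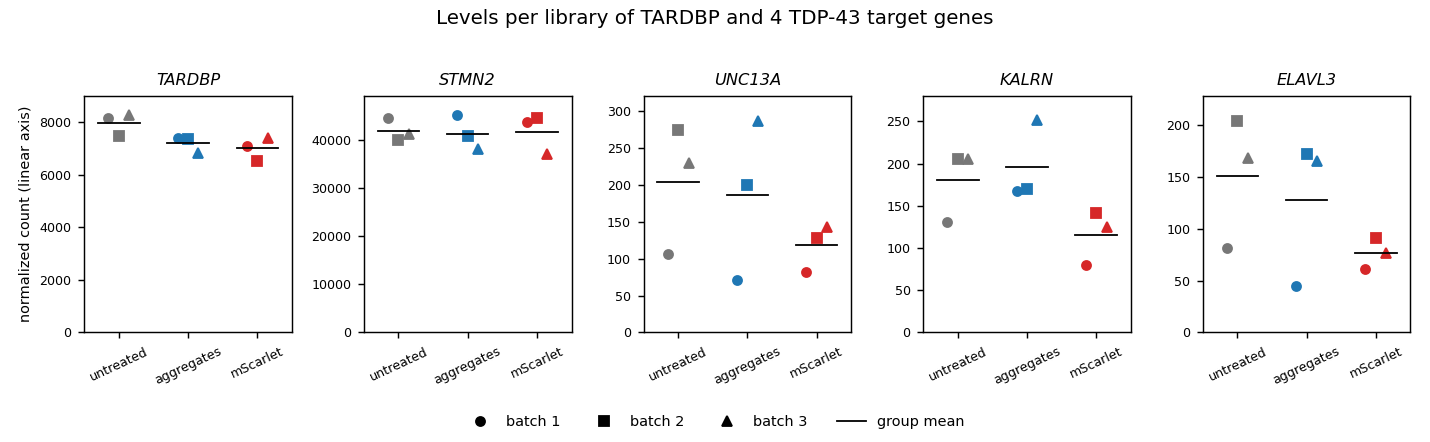
Normalized counts (linear axis from 0) of TARDBP, STMN2, UNC13A, KALRN and ELAVL3 in each of the 9 libraries, grouped by treatment, with a marker shape per batch and a line at the group mean. Group means of STMN2 lie between 41320 and 41930, while UNC13A, KALRN and ELAVL3 are lowest on average in the mScarlet group, at 118, 116 and 76.1, and each of these 3 is lower in the mScarlet than in the untreated library of the same batch in all 3 batches.

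All 6 genes that rose with aggregates also rose in mScarlet against untreated cells, where 0.309 shared genes would arise from independent lists of 6 and 724 among 14039, and RNF212, which fell with aggregates, was not called there (limma adjusted p = 0.0899, or 0.0198 with the block). MGP reached 52650 ± 12070 normalized counts in the mScarlet libraries. With the block, 209 genes were higher in both, of 218 and 1942, against 30.2 from independent lists, and 12 were lower in both, of 16 and 1705, against 1.94. Unchanged groups simulated with shared untreated libraries and the block gave at most 1 of these shared calls over 100 simulations, against 221. Log2 changes of the 2 comparisons correlated across genes, which are not independent replicates, with r = 0.61. Simulated unchanged groups that share their untreated libraries gave a mean r of 0.50 and at most 0.53 over 100 simulations, and at most 1 shared call. The covariance was 0.17 against 0.0533 in the simulations, a difference of 0.117. The simulations drew each gene on its own, whereas real genes move together (estimated correlation 0.868 among ribosomal proteins). They therefore cannot give the spread of r that unchanged groups would show. Unchanged groups also yield few calls, so the simulated shared calls do not test whether called genes overlap through the shared libraries. The untreated libraries are too few to be split, and part of the excess may come from sharing them.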

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

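Removal of GC and length trends, the fit to batches 2 and 3 only and the gene-by-gene library weights were chosen after results had been seen; the other alternatives were set beforehand. Of 5885 values of named genes over the alternatives, 5375 stayed on their side of the threshold, 226 of them changing sign without a call; 411 no longer passed, 96 newly passed and 3 reversed. Of 1782 list values these numbers were 1609 (68 changing sign), 113, 56 and 4. Results without a call in the main fit could not lose one. In aggregates against untreated, mScarlet against aggregates and mScarlet against untreated, 7, 34 and 72 of the 227 named gene results had a call. Of the 81 list results 8, 13 and 18 had one. Where no cause is given, the cause was not tested. Counts below are for aggregates against untreated, mScarlet against aggregates and mScarlet against untreated, in that order, against 7, 128 and 903 genes, 8, 13 and 18 lists and an overlap of 6.

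With the replicate number as a block 234, 2864 and 3647 genes passed, and the overlap was 221; list counts stayed within 1.5 times. It ended no gene or list call and, beyond the values given beside the results, changed no other gene or list call that the report prints; genes it newly called in comparisons where the report gives them no value are only in these counts. By edgeR the first count was 2, the other 2 staying within 1.5 times; edgeR with the block called 238, 2718 and 3556 and DESeq2 151, 698 and 1638. Rescaling by TMM, median-of-ratios or quantiles and a pseudocount of 0.5 left each count within 1.5 times, but ended some calls and added others. Added under quantile normalization were stress granule proteins (median -0.25, camera adjusted p = 0.0037) and nuclear transport (-0.17, 0.0031), both downward in the second comparison. HNRNPA1, CAPRIN1 and CLTC then fell in the third (limma adjusted p = 0.048, 0.0123 and 0.0171). Median-of-ratios added heparan sulfate genes upward in the first (0.13, camera adjusted p = 0.0484). These added list calls were not tested with an estimated correlation. Under quantile normalization the lists of G2 and M phase (median -0.12, camera adjusted p = 0.0809) in the first, heat shock (0.01, 0.349), proteasome (0.08, 0.145) and ribosomal proteins (0.07, 0.0706) in the second, and lysosome (0.04, 0.088) and ribosomal proteins (0.05, 0.172) in the third no longer passed. The same held for CCL7, CHGA, PCDHB14, DUSP6 and LGALS1 in the second (limma adjusted p = 0.0522, 0.0526, 0.0552, 0.0603 and 0.0689) and PSMB3, PSMA7, CTSB, FDFT1 and NPY in the third (0.0811, 0.152, 0.131, 0.0992 and 0.0977). With TMM CTSB did not pass (0.0506), and with a pseudocount of 0.5 neither did ANXA1 and MGP in the first (0.0569 for both) or CCL7, SLC14A1, CC2D1A, ZCCHC12 and PCDHB14 in the second (0.0502, 0.0675, 0.0502, 0.0522 and 0.053). With a pseudocount of 5 the first 2 counts were 12 and 195 and the overlap 11. With no filter no gene passed in the first comparison, by limma, and the overlap was 0, whereas 492 genes had an unadjusted p under 0.05 with the filter. Tested genes with a mean of at least 50 gave 80 for the second, and fits to only the 2 groups compared gave 0 and 74 for the first 2, from fewer samples.

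Library weights by the default method, which did not converge, gave 1965, 6470 and 4706 genes and the gene-by-gene method 954, 4413 and 3573. Without GC and length trends 4, 444 and 1603 genes passed, and with the block as well 227, 2975 and 3998. Batches 2 and 3 only gave 2, 1933 and 2325 genes and 5 lists for the first comparison. Camera with an estimated correlation called 0 lists in each comparison, with lowest adjusted p of 0.138, 0.114 and 0.103, and fry 0, 4 and 11.

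Leaving out each library in turn gave 0 to 91, 17 to 1358 and 452 to 1396 genes and 7 to 14, 11 to 16 and 15 to 19 lists; the 14 lists came without untreated replicate 1. Reversed were ribosomal proteins in aggregates against untreated cells without untreated replicate 1 (median 0.15), G2 and M phase there without aggregates replicate 1 (0.13), S phase there without the same library by camera's direction only (median 0.24 against 0.05, ranging from -0.07 to 0.24 over the libraries left out), and ribosomal proteins in mScarlet against untreated cells without GC and length trends (-0.01). With those trends removed and the block, GABARAPL2 and CKS1B in mScarlet against aggregates cells (-0.24 and -0.26) and CKS2 against untreated cells (-0.21) reversed. Depth limits low genes: 3 reads correspond to 2.44 to 3.98 normalized counts per library.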

Other observations

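Gene groups in the next paragraph, and all tests below other than those of GC content on inflammatory genes, of immune transcripts under 10 normalized counts and of other splits of the libraries, were chosen after results had been seen; the GC test of inflammatory genes was set before its own result was seen, with a correction chosen after the data were seen.

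Several neuroendocrine genes differed between mScarlet and untreated cells. At the imprinted cluster on chromosome 14, DLK1 fell from 107000 ± 10600 to 49800 ± 4380 normalized counts and RTL1 from 3430 ± 1500 to 687 ± 179 (SD, n = 3 each), with limma adjusted p = 0.00881 and 0.02, and DIO3 stayed near 0 in all groups. Secretory granule genes split: CHGB fell from 21000 ± 5820 to 7840 ± 764, SCG3 from 7250 ± 1650 to 3880 ± 717 and the prohormone convertase gene PCSK1 from 13.2 ± 4.67 to 0.697 ± 1.21 (limma adjusted p = 0.0327, 0.0345 and 0.0211). In the mScarlet group PCSK1 lay under the floor of 3 reads per library. No counting interval was made for it, so the size of its fall is uncertain. SCG2, SCG5, VGF, PCSK2 and CPE did not pass, with log2 changes of -0.15, -0.05, 0.18, -0.17 and 0.28 (limma adjusted p = 0.803, 0.868, 0.822, 0.853 and 0.428). Of the neuropeptide genes VIP rose from 939 ± 409 to 4380 ± 2670 and NPY from 12200 ± 3220 to 28500 ± 9110 (limma adjusted p = 0.0275 and 0.0226), GAL passed only with the block (limma adjusted p = 0.0119 against 0.198) and ADM did not pass (0.399).

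The NF-kB, interferon and mesenchymal lists stood above the other genes in mScarlet against aggregates libraries by camera (adjusted p = 0.114, 0.318 and 0.375 with an estimated correlation), with 6, 3 and 3 members higher by group alone. With the block, removing GC and length trends left the median of their 70 measured members at 0.80 against 0.76. Its 95% interval of 0.55 to 1.09 resampled the members, so it does not cover the spread between libraries. Of the members 35 were called higher before and after. These values argue against those trends as the whole cause. A larger share of S-type cells would lower adrenergic markers alike, and with the block 15 of 26 fell and 2 rose against untreated cells. VIP and CHGA moved apart by 3.5 on the log2 scale there (SE 0.22, with the block). As the highest and the lowest of the 26, picked after results were seen, they cannot decide the question. CAV1 had 0 reads in all libraries, PRRX1 had 0 in the mScarlet group and COL1A2 at most 6.63 normalized counts there. Yet 13 of 24 measured S-type markers rose against untreated cells and none fell. Whether a larger share of S-type cells took part cannot be told apart, and a change of state within the cells stays open. Immune cells as the source of the whole summed rise are argued against. The 7 core immune transcripts together changed by -6.16 normalized counts on average (95% interval of the mean -20.1 to 7.82, n = 3 pairs). The summed list members rose by 26725 to 78737 in single pairs. The upper end is 0.0292% of the lowest rise, against the 1% taken as the least such cells would bring. Abundant members weigh most in that sum, such as B2M, at 18390 to 37820 in aggregates and 50120 to 63900 in mScarlet libraries. The list member PTGS2 lay at 29.25 to 53.08 in mScarlet libraries, so the sum cannot decide the source of such low genes. Whether a few immune cells were present cannot be told apart: 5 of the 7 stayed under 10 normalized counts in each mScarlet library, short of the 6 set beforehand. In those libraries CD14 reached 21.2 and CSF1R 14.6 (32.3 in an aggregates library), while TYROBP, LYZ and AIF1 had 0. The treatment label of the mScarlet group names transduction of an mScarlet plasmid, whose effect cannot be separated from reporter activation here. That effect was not tested and stays open, as does any further handling, which the sources used here do not give.

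The list of TDP-43 targets stood below the other genes in mScarlet against aggregates libraries by camera (adjusted p = 0.434 with an estimated correlation), with 0 of 31 members past the limma test by group alone. With the block 12 were lower and 2 higher. Removing GC and length trends in that fit took the median from -0.35 to -0.21, with 11 lower and 2 higher. Its 95% interval of -0.38 to -0.06 resampled the list members, so it does not cover the spread between libraries. Whether those trends make part of the fall cannot be told apart. A fall of neuronal genes in general is a candidate explanation: the targets lay 0.14 above 39 axon and synapse genes that are not targets (medians -0.35 and -0.49, permutation p = 0.249 over 100000 resamples of genes). A loss of TDP-43 function strong enough to lower STMN2 mRNA by 1.5-fold over all cells of the libraries is argued against by its log2 change of 0.01 with a 95% interval of -0.22 to 0.25. Inclusion of cryptic exons was not measured, so a loss of function that leaves STMN2 mRNA at its level stays open.

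More genes passed between mScarlet and aggregates cells with the replicate block than without it. If GC and length trends that differ between batches were the whole cause, removing them should give as many calls without the block, but 444 genes passed against 2864, which argues against them as the whole cause. Other differences between batches, such as culture or library preparation, stay open and were not tested.

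Splits of 6 libraries into 3 and 3 number 10, too few for a share under 0.05. In aggregates against untreated cells the real split called 7 genes and the highest other 0, and in mScarlet against untreated cells 903 and 0, so that 1 of 10 splits reached the real count in each. In mScarlet against aggregates cells 2 of 10 did: the real split called 128 genes, and 2571 were called by the split of aggregates replicate 1 and mScarlet replicates 1 and 2 from the other 3 libraries, which follows the sign of the GC trend and points to a structure of the libraries other than group. That split parts 1 pair of same-numbered libraries and called 0 genes with the block, by limma, where the real split called 2864. Among the 4 splits that part all 3 pairs, as the real split does, the highest other count was 0 without the block in each comparison.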
